A study of Mus musculus with 10 samples.

How the data were processed

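Gene expression was measured on Affymetrix arrays in 10 cultures of mouse CD4+ T cells. Per the labels, naive cells were sorted by flow cytometry, activated on plate-bound antibodies to CD3 and CD28 (10 µg/ml) with an antibody to IFN-γ (10 µg/ml) in all cultures, and given cytokines for 3 to 4 days. The deposited values are probe set signal intensity values made with GCOS and MAS5, per the submitters' processing notes, which give no version. In 8 arrays the mean after trimming 2% at each end was exactly 500, the lowest signal was 1 and median signals were 50.1 to 75.4. In the 2 arrays of the inhibitor pair the trimmed means were 415 and 411, the lowest signal was 7 and all values were whole numbers, against 10.6% to 11.6% of values elsewhere. The pair had thus been processed in another way and was compared only within itself. The doses of IL-6 and TGF-β are not stated for the pair.

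The table held 45101 probe sets. Left out were 64 controls, 932 probe sets that an annotation of 2016 gives several gene symbols and 9160 that it does not name, while 34958 had 1 symbol. These numbers count 13 controls with a symbol under both headings. Signals were analysed as log2(signal + 20), where 20 is the 25th percentile of all signals, so fold changes of genes with signals near or under 20 are smaller than their plain ratios. Kept were probe sets above the median of their array in at least 2 of the 8 replicated arrays. Each gene was represented by its probe set with the highest mean, which left 11873 genes, of which 5577 had more than 1 passing probe set. In every named gene that passed the test, all passing probe sets had the same sign. Probe sets for Ifng and Foxp3 did not pass the filter.

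The 4 groups of 2 arrays were fitted together in limma 3.58.1 under R 4.3.3 with a trend in the prior variance, which left 4 residual degrees of freedom. The 6 comparisons were tested with limma's moderated test, 2-sided, at an adjusted p (Benjamini-Hochberg) below 0.05 in each comparison over all genes. Errors beside signals are SD and errors beside log2 fold changes are SE. The labels do not say whether replicates are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

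Named genes were the 10 highest and 10 lowest log2 fold changes in the comparison of IL-23 with TGF-β1, and the 6 highest and 6 lowest in the others, among genes past the test whose arrays did not overlap between groups. To these were added up to 4 members of each list and 15 genes fixed in advance, of which 9 were tested. Predicted and unnamed transcripts were passed over. Comparisons, lists, filter, tests and most alternatives were chosen before the data were examined.

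Lists of 301 genes, 271 of them matched, were written for Th17, Th1, Th2 and regulatory T cells, TGF-β/SMAD and IL-6/STAT3 responses, pathogenic and non-pathogenic Th17 cells, interferon-stimulated genes, cell cycle, glycolysis and hypoxia, cholesterol synthesis, naive and memory T cells, stress and amino acid response, cytotoxic genes, and B, myeloid, dendritic, CD8 T, NK, γδ and NKT, and erythroid cells. With at least 3 measured members, 19 of 22 lists were tested by camera with a preset correlation of 0.01, adjusted over all 114 tests, and again by camera with the correlation estimated from the data and by fry. Measured members of these lists are those that passed the filter. Members were also adjusted over their list alone. Such counts are corrected for fewer tests than those over all genes, and not over the lists or comparisons, so they are a looser measure. In the inhibitor pair ratios were counted at more than 2-fold without a test, and list medians were set among 10000 random lists of the same size matched on mean expression. By that measure the pathogenic, Th1, interferon and cytotoxic lists lay at percentile 100, and the non-pathogenic, TGF-β/SMAD and Th17 lists at percentile 0. The regulatory list lay at percentile 0.02, naive and memory genes at 99.95, cell cycle at 99.1, Th2 at 98.9, B cell at 97.6, dendritic at 95.8, stress at 94.7, glycolysis at 50.6, IL-6/STAT3 at 46.5 and cholesterol at 26.4. The pair has no replicate arrays, and random lists do not allow for genes of a list that vary together. An extreme percentile thus cannot tell an effect of the inhibitor from another difference between these arrays. Cell cycle reached 99.1 with a median log2 ratio of 0.11 and 0 of 31 genes past 2-fold. The percentiles only describe the pair and are not a test.

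Procedures were tested on 10 simulated data sets with 200 genes changed in the IL-23 group of each. They used the mean of each gene over the 8 replicated arrays and its spread in the fit of the 4 groups, as moderated by limma. In the comparison of IL-23 with TGF-β1, 13.7% of 2-fold, 81.8% of 4-fold and 99.8% of 16-fold changes were recovered, and 5.28% of calls were false. Recovery depends on the number of changed genes, here set at 200. The rates thus need not hold where few genes change, as for IL-23 added to IL-6 and IL-1β. Camera called a shifted list in 10 of 10 data sets and the others in 0 of 180 tests. Genes were simulated as independent of each other. These rates thus do not show how camera behaves when the genes of a list vary together. Alternatives were quantile normalization over 10 or 8 arrays, scaling to equal medians, an added constant of 1 or 80, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, all probe sets, only the arrays compared, no trend, a robust fit, the replicate number as a block, and each array left out in turn.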

Results

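Naive CD4+ T cells (CD62L+, CD44-, CD25-) were sorted from spleen and lymph nodes of mice aged 6 to 8 weeks and activated for 3 to 4 days without serum on plate-bound antibodies to CD3 and CD28, with IFN-γ neutralised in every culture. Expression arrays were made from 4 kinds of culture with 2 replicates each: no added cytokine, IL-6 with IL-1β (20 ng/ml each), IL-6 with IL-1β and IL-23 (50 ng/ml), and IL-6 with IL-1β and human TGF-β1 (0.5 ng/ml). A further pair of cultures, with 1 array each, had received IL-6 and TGF-β with or without a kinase inhibitor of the type I TGF-β receptor (1 µM). Over the 11873 genes tested, replicates of a culture correlated at 0.944 to 0.968. Some arrays of different cultures with the same replicate number correlated as well or better. IL-6 with IL-1β correlated with the same plus IL-23 at 0.9775 for replicate 1 and 0.9805 for replicate 2. Among arrays of other groups, 7 of the 8 replicated arrays correlated best with one of their own replicate number. The first principal component (52.8% of the variance) set the cultures without cytokine apart from the rest, replicate 1 more than replicate 2 (-92.5 and -45), and the second (15.3%) set the cultures with TGF-β1 apart from the other 6.

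Th17 cells made with IL-23 and those made with TGF-β1 both had high Il17a signals but differed in effector and regulatory genes. Il17a, which encodes the cytokine that defines Th17 cells, had a mean signal of 17510 ± 1630 (SD, n = 2) with IL-23 and 20610 ± 2190 (n = 2) with TGF-β1, a log2 difference of -0.23 (95% interval -0.86 to 0.40). Il10, which encodes an anti-inflammatory cytokine, was 47.2-fold lower with IL-23, at 48.7 ± 8.49 against 3234 ± 574 (log2 fold change -5.56 ± 0.31 SE, adjusted p = 0.000424). Cxcr3, which encodes a chemokine receptor typical of Th1 cells, was 18.1-fold higher with IL-23, at 2595 ± 28.7 against 129.5 ± 52.9 (4.18 ± 0.31, adjusted p = 0.00155). Of 11873 genes, 54 were higher and 41 lower with IL-23 at an adjusted p below 0.05 by limma's moderated test.

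Among the genes higher with IL-23 were Nkg7, found in granules of cytotoxic lymphocytes (1306 ± 1160 against 13.1 ± 8.34; 5.00 ± 0.73, adjusted p = 0.0227). Trat1, whose product associates with the T cell receptor, was higher as well (1142 ± 425 against 29.75 ± 4.17; 4.50 ± 0.38, adjusted p = 0.00226). Il33, the gene of an alarmin, was 19.4-fold higher (732 ± 118 against 19.95 ± 14.8, adjusted p = 0.00226). Ccl3, which encodes an inflammatory chemokine, was 17.2-fold higher (464.2 ± 190 against 7.2 ± 3.82, adjusted p = 0.007). S100a4 (4.09 ± 0.50, adjusted p = 0.0133), Crtam (4.15 ± 0.70, adjusted p = 0.0366), Dcn (3.90, adjusted p = 0.0142) and Plcd4 (3.89, adjusted p = 0.0104) were also higher. Igfbp7 stood just past the threshold (4.41 ± 0.80, adjusted p = 0.0499) and kept its call in 3 of 16 other settings. With IL-6 and IL-1β alone the signals were 1188 for Nkg7, 1977 for Trat1, 309.8 for Il33, 387 for Ccl3 and 3480 for S100a4. Without cytokine they were 676.4, 1278, 36.2, 2436 and 101.5, in that order. A higher value than with TGF-β1 thus does not show that IL-23 raised these genes.

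Gpr15, which encodes a receptor that guides T cells to the large intestine, was 60.1-fold lower with IL-23 (15.8 ± 7.78 against 2156 ± 653; -5.91 ± 0.42, adjusted p = 0.00155). Ahr, the gene of a ligand-activated transcription factor that acts in Th17 cells, was 17.9-fold lower (412.4 ± 237 against 7137 ± 557, adjusted p = 0.0142). Cyp1b1, a target of that factor, was 18.1-fold lower (61.8 ± 28.1 against 1425 ± 217, adjusted p = 0.00418). Nt5e, which encodes the ectoenzyme CD73, was 14.5-fold lower (98.9 ± 16.4 against 1762 ± 705, adjusted p = 0.00226). Maf, which encodes a transcription factor that drives Il10, was 3.5-fold lower (1870 ± 212 against 6609 ± 1080, adjusted p = 0.0435). Sema6d (-4.76, adjusted p = 0.0196), Serpinb1a (-4.39 ± 0.67, adjusted p = 0.0256), Dusp4 (-3.97 ± 0.33, adjusted p = 0.00226), Pdpn (-3.48, adjusted p = 0.0133), Cldnd1 (-3.48, adjusted p = 0.00476) and Ccl20 (-3.46 ± 0.51, adjusted p = 0.0243) were lower as well. Tbx21, the gene of the Th1 transcription factor T-bet, had signals of 1090 ± 837 with IL-23 and 42.9 ± 27.2 with TGF-β1. It did not pass the test in the main fit (3.97 ± 0.77, 95% interval 2.22 to 5.72 without adjustment, adjusted p = 0.0728). With the replicate number added as a block it passed limma's test (adjusted p = 0.00324), though the labels do not say what that number stands for. Csf2, which encodes GM-CSF, had a difference of 0.04 (95% interval -1.86 to 1.95), and Il9 (-4.59 ± 1.01, adjusted p = 0.12) did not pass in the main fit.

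**Figure D1:**
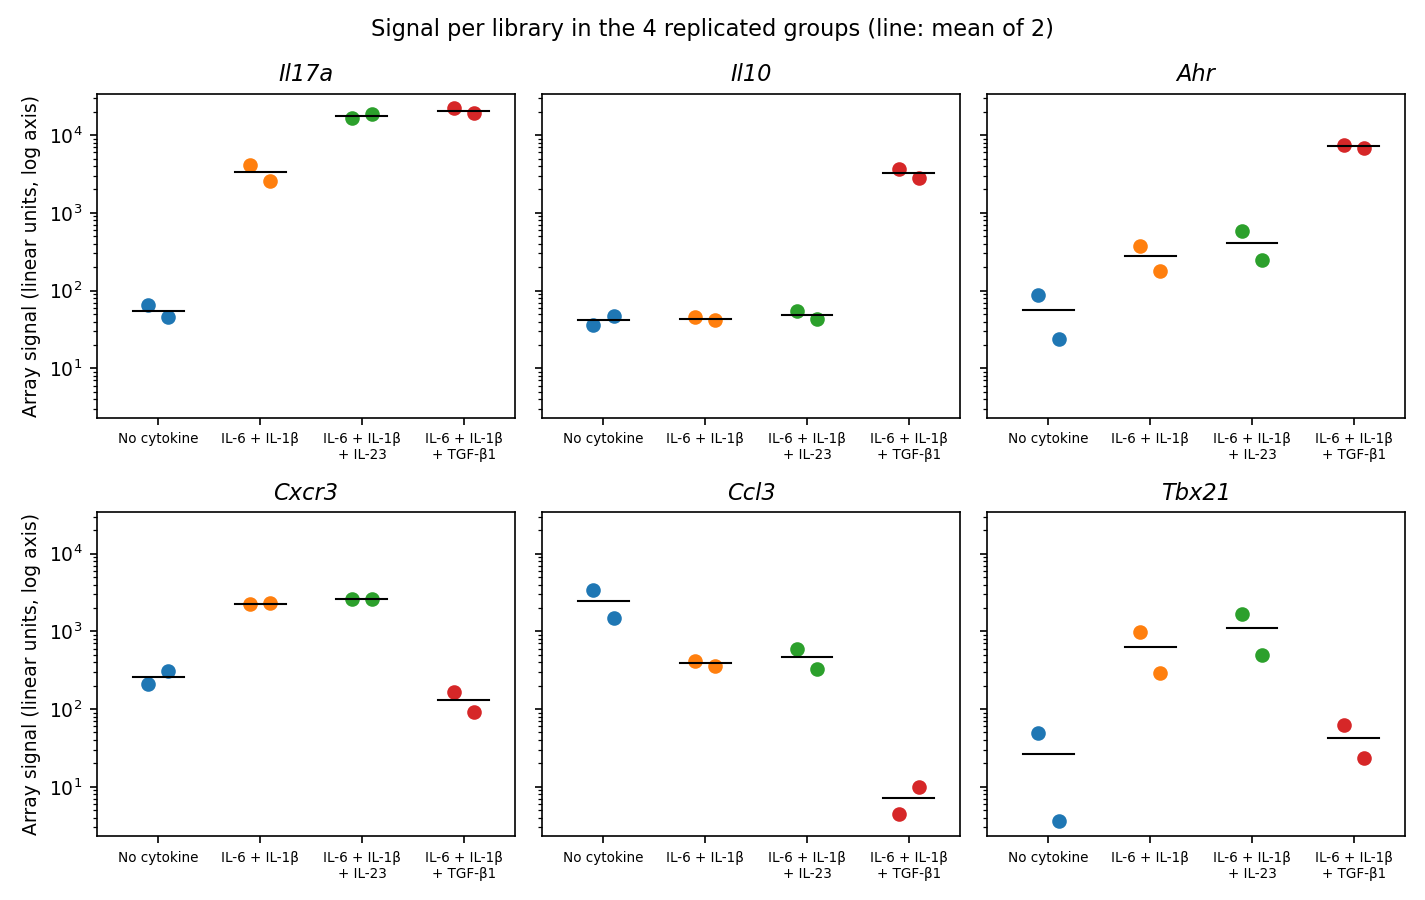
Signal of 6 genes on a log axis in the 8 replicated cultures, in groups by added cytokine, where each point is 1 array and each line the mean of 2. With TGF-β1, Il10 and Ahr reached means of 3234 and 7137 and Ccl3 dropped to 7.2.

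Lists of genes written from published work on Th17 cells, not chosen on these samples, split along the same contrast. Of 14 measured members of the pathogenic Th17 list, 3 were higher with IL-23 (Ccl3, Ccl5, Il18r1), none was lower and 11 did not pass the test over all genes. When adjusted over the list alone 8 were higher, and the median log2 fold change of the list was 1.47 (camera adjusted p = 3.12e-11, adjusted p = 0.0638 with an estimated correlation). With IL-23 against IL-6 and IL-1β alone, the median of this list was -0.03 and it was not called. Of 7 measured members of the non-pathogenic list, 3 were lower with IL-23 (Il10, Ahr, Maf) and 6 were lower when adjusted over the list alone. Their median was -1.81 (camera adjusted p = 8.05e-12, adjusted p = 0.0638 with an estimated correlation). Of 15 Th1 genes, Cxcr3, Il18r1 (3.10 ± 0.55, adjusted p = 0.0477) and Ccl5 (2.93 ± 0.46, adjusted p = 0.0306) were higher. Over the list alone 7 were higher and 1, Cxcr6, was lower (median 0.67, camera adjusted p = 1.19e-06, adjusted p = 0.09 with an estimated correlation).

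TGF-β/SMAD response genes leaned lower with IL-23 (median -0.71 over 16 genes, camera adjusted p = 7.65e-06, adjusted p = 0.0945 with an estimated correlation). Skil, whose product restrains SMAD proteins, was lower (-1.30, adjusted p = 0.0435), Id3 was higher (2.27 ± 0.37, adjusted p = 0.0315). Over the list alone 5 were lower and 1 higher. Interferon-stimulated genes leaned higher (median 0.48 over 19 genes, camera adjusted p = 1.21e-05, adjusted p = 0.183 with an estimated correlation). Of these Xaf1 (2.58, adjusted p = 0.0315) and Trim30a (2.33, adjusted p = 0.0104) passed the test and 3 were higher over the list alone. The regulatory T cell list had a median of -0.48 (camera adjusted p = 0.00884, adjusted p = 0.335 with an estimated correlation). Nt5e was lower and Nrp1 higher (2.33, adjusted p = 0.0424), and the list lost its call without replicate 1 with IL-23 (adjusted p = 0.0788). Among 9 cytotoxic genes Nkg7 and Serpinb9 (3.15, adjusted p = 0.0133) were higher and Klrd1 was lower (-3.41 ± 0.50, adjusted p = 0.0227). Over that list alone 4 were higher and 2 lower, with a median of 0.58 (camera adjusted p = 0.0164, adjusted p = 0.226 with an estimated correlation). That call was lost without replicate 2 with IL-23 (adjusted p = 0.0608) and without replicate 1 with TGF-β1 (adjusted p = 0.0968).

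The Th17 list itself had a median of -0.27 over 10 genes with IL-23 relative to TGF-β1, with Ahr and Ccl20 lower and 8 not past the test (camera adjusted p = 0.0408, adjusted p = 0.466 with an estimated correlation). Its call was lost without replicate 2 with IL-23 (adjusted p = 0.433), without replicate 1 with TGF-β1 (adjusted p = 0.313), and without replicate 1 or 2 of the cultures without cytokine (adjusted p = 0.0556 and 0.0606). Stress and amino acid response genes had a median of 0.17 with none of 14 past the test (camera adjusted p = 0.0263, adjusted p = 0.438 with an estimated correlation). This call was lost without replicate 2 with IL-23 (adjusted p = 0.402) and without replicate 1 with TGF-β1 (adjusted p = 0.456). Its mean of 0.32 was 0.54 without replicate 1 with IL-23 and 0.61 without replicate 2 with TGF-β1. Of 3 natural killer (NK) receptor genes, Klrd1 and Klre1 (-2.94, adjusted p = 0.0104) were lower (median -2.94, camera adjusted p = 7.68e-05, adjusted p = 0.207 with an estimated correlation). The cell cycle list was not called (median -0.06 over 31 genes, adjusted p = 0.851), but its mean over the list, centred on all 8 arrays, was -1.05 and 0.125 in replicate 1 and 2 with IL-23 against -0.391 and -0.481 with TGF-β1. The median near 0 thus averages arrays with IL-23 that lie on both sides of those with TGF-β1.

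With 1 array left out, its group has 1 array and the spread comes from the other groups, so counts can be lower whichever array is removed. The count of 95 genes was 9 and 23 without replicate 1 and 2 with IL-23, and 10 and 21 without replicate 1 and 2 with TGF-β1. Of the 30 named genes that passed, 22, 15, 23 and 14 lost the call in those 4 fits, in that order. All 30 kept their direction, and Trat1, Cxcr3, Gpr15, Il10, Dusp4 and Nt5e kept the call in each, while the other 24 lost it in at least 1.

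Adding TGF-β1 to IL-6 and IL-1β raised Il17a 6.32-fold, from 3332 ± 1110 to 20610 ± 2190 (log2 fold change 2.66 ± 0.28, adjusted p = 0.00516). Il10 rose 50.7-fold, from 43.75 ± 3.32 to 3234 ± 574 (5.66 ± 0.31, adjusted p = 0.000362), and Pdpn, which encodes the mucin-like glycoprotein podoplanin, rose 58.3-fold, from 89.15 ± 5.87 to 6393 ± 1170 (5.87 ± 0.43, adjusted p = 0.00113). Cxcr3 was 15.9-fold lower with TGF-β1, going from 2275 ± 49 to 129.5 ± 52.9 (-3.99 ± 0.31, adjusted p = 0.00114). In all, 50 genes rose and 48 fell with TGF-β1.

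Gpr15 (5.62 ± 0.42, adjusted p = 0.00113), Ahr (4.67 ± 0.54, adjusted p = 0.00712), Cyp1b1 (4.62 ± 0.40, adjusted p = 0.00182), Cldnd1 (4.15, adjusted p = 0.00158), Nt5e (3.59, adjusted p = 0.00264) and Maf (2.77 ± 0.31, adjusted p = 0.00687) rose with TGF-β1. Trat1 (-5.25 ± 0.38, adjusted p = 0.00113), Nkg7 (-4.93 ± 0.73, adjusted p = 0.0201), Akr1c18 (-4.51, adjusted p = 0.0367), Crtam (-4.07, adjusted p = 0.0367) and S100a4 (-3.99, adjusted p = 0.00925) fell. Gata3, the gene of the transcription factor that sets the Th2 program, was also lower, at 50.4 against 334.6 (-2.34, adjusted p = 0.00743). Tbx21 (-3.21 ± 0.77, adjusted p = 0.134), Gzmb (-4.72, adjusted p = 0.0687), Il9 (3.21, adjusted p = 0.324) and Csf2 (-0.28) did not pass the test in the main fit. With the replicate number, which the labels do not explain, added as a block, Tbx21 and Gzmb passed limma's test (adjusted p = 0.00484 and 0.00403).

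The published lists were tested again in this comparison, which shares both arrays with TGF-β1 with the one before, so that opposite signs are partly built in. Of 7 non-pathogenic genes, 3 rose (Il10, Ahr, Maf) and 6 rose over the list alone (median 2.77, camera adjusted p = 9.18e-13, adjusted p = 0.0638 with an estimated correlation). Of 14 pathogenic genes, Ccl3 fell (-3.91, adjusted p = 0.006) and 8 fell over the list alone (median -1.3, camera adjusted p = 1.06e-09, adjusted p = 0.0642 with an estimated correlation). Of 10 Th17 genes, Il17a, Ahr and Ccl20 (3.47, adjusted p = 0.0201) rose and 4 rose over the list alone (median 0.98, camera adjusted p = 1.81e-06, adjusted p = 0.183 with an estimated correlation). TGF-β/SMAD response genes included Skil, which rose (1.54, adjusted p = 0.0201), and Id3, which fell (-2.64, adjusted p = 0.017). Over the list alone 7 rose and 1 fell, with a median of 0.78 (camera adjusted p = 2.45e-06, adjusted p = 0.09 with an estimated correlation). Of 15 Th1 genes Cxcr3 fell, and over the list alone 6 fell and 1 rose (median -0.82, camera adjusted p = 5.54e-05, adjusted p = 0.12 with an estimated correlation). Interferon-stimulated genes leaned lower (median -0.40, camera adjusted p = 0.000229, adjusted p = 0.219 with an estimated correlation). Of these Xaf1 (-2.64, adjusted p = 0.0272) and Trim30a (-2.27, adjusted p = 0.00743) fell.

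All 31 cell cycle genes had lower values with TGF-β1 than with IL-6 and IL-1β alone (median -0.54, camera adjusted p = 1.19e-06, adjusted p = 0.487 with an estimated correlation), though none passed the test singly. Klrd1 (3.51, adjusted p = 0.0178) and Klre1 (3.60, adjusted p = 0.00264) rose among the 3 NK receptor genes (median 3.51, camera adjusted p = 1.38e-06, adjusted p = 0.183 with an estimated correlation). Of the cytotoxic genes Klrd1 and Ctsw (2.57, adjusted p = 0.0186) rose while Nkg7 and Serpinb9 (-3.31, adjusted p = 0.00712) fell, and the list was not called (camera adjusted p = 0.194). IL-6/STAT3 response genes had a median of 0.31 with none of 14 past the test (camera adjusted p = 0.017, adjusted p = 0.299 with an estimated correlation). The call was lost without replicate 2 of IL-6 with IL-1β (adjusted p = 0.0913) and without replicate 1 with TGF-β1 (adjusted p = 0.186). The regulatory T cell list was not called (adjusted p = 0.0692), although Nt5e rose and Nrp1 fell (-3.38, adjusted p = 0.00743). The Th2 list was not called either (adjusted p = 0.466), with a median of 0.42 and a mean of -0.26.

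The count of 98 genes was 17 and 27 without replicate 1 and 2 of IL-6 with IL-1β, and 15 and 50 without replicate 1 and 2 with TGF-β1. Of the 26 named genes that passed, 15, 12, 17 and 7 lost the call in those 4 fits, in that order. None changed direction, and Il17a lost its call only without replicate 1 with TGF-β1 (adjusted p = 0.0664). Pdpn, Il10, Gpr15, Cyp1b1, Cldnd1, Trat1, Cxcr3 and Nt5e kept theirs in each, and the other 18 lost it in at least 1.

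**Figure D2:**
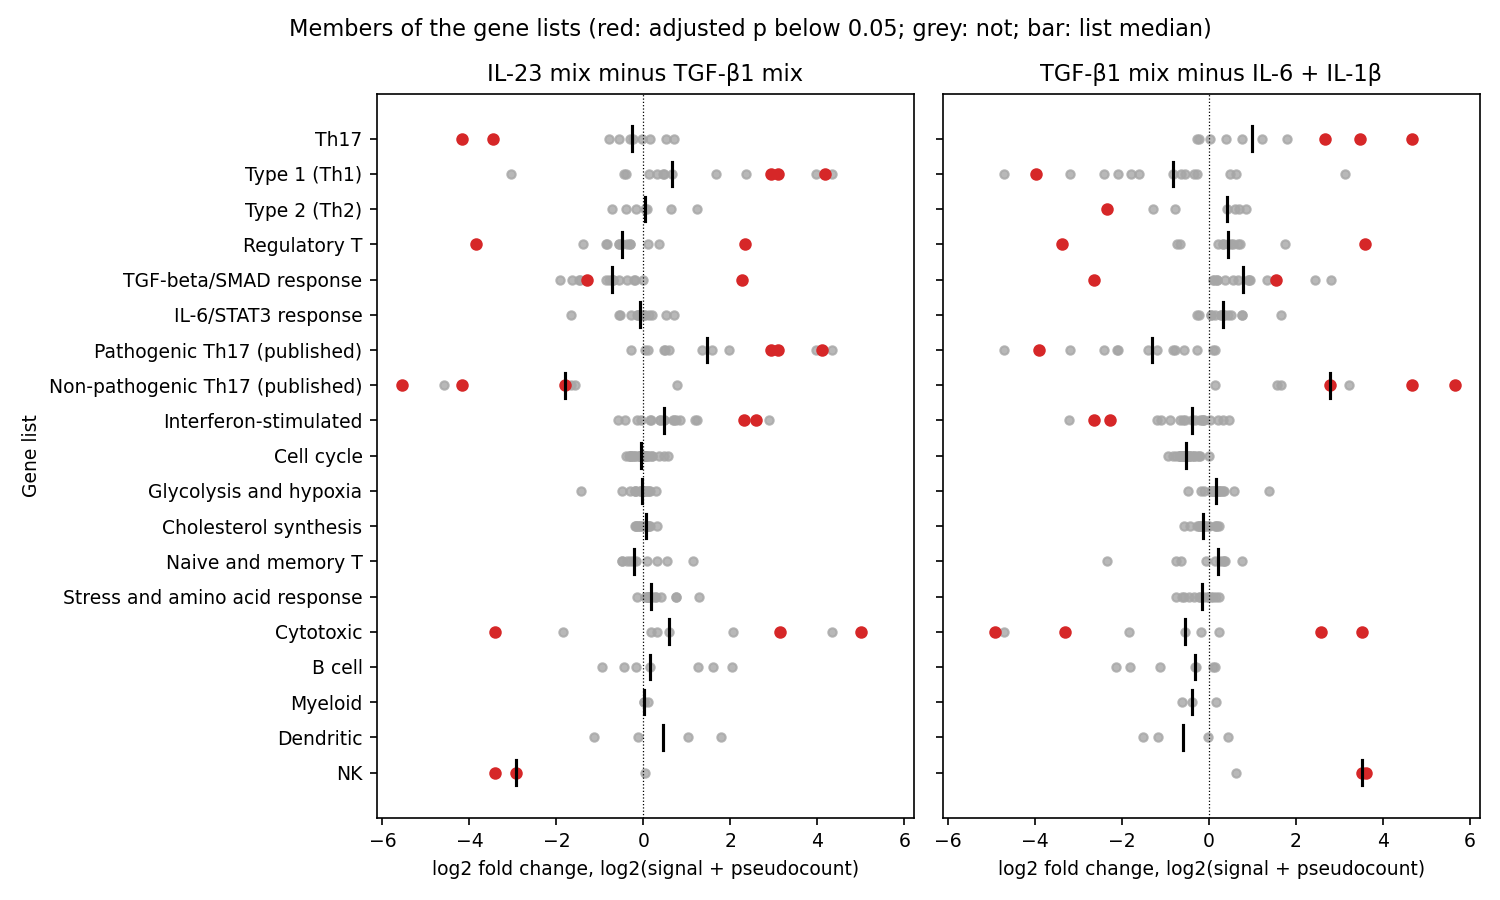
Log2 fold changes of the members of each list, for IL-23 against TGF-β1 and for TGF-β1 added to IL-6 and IL-1β. Each point is 1 gene, red with an adjusted p below 0.05 and grey otherwise, and each bar is the list median (-1.81 and 2.77 for the non-pathogenic list, with opposite signs partly built in since both panels share the TGF-β1 arrays).

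Adding IL-23 to IL-6 and IL-1β left no gene past the test. Il17a had the lowest adjusted p (0.151), with signals of 17510 ± 1630 with IL-23 and 3332 ± 1110 without it. That is a 5.37-fold difference in value (log2 2.42 ± 0.28, 95% interval 1.80 to 3.05 without adjustment). Il10 (0.10, 95% interval -0.61 to 0.81), Cxcr3 (0.19, 95% interval -0.52 to 0.90) and Ahr (0.51, 95% interval -0.71 to 1.73) had intervals that included 0, as did Tbx21 (0.77, 95% interval -0.99 to 2.51) and Csf2 (-0.24, 95% interval -2.15 to 1.67). By limma's moderated test 0 of 11873 genes passed, with 177 at an unadjusted p below 0.05, and the robust and trend-free versions of the fit and every other setting also gave 0. Across those settings the lowest adjusted p of Il17a was 0.0912.

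Of the 10 Th17 genes, 9 had higher values with IL-23, and over the list alone Il17a rose (median 0.36, camera adjusted p = 2.16e-06, adjusted p = 0.183 with an estimated correlation). The list mean of 0.64 was 0.33 without replicate 2 of IL-6 with IL-1β (adjusted p = 0.0196) and 0.34 without replicate 1 with IL-23 (adjusted p = 0.0296). Hlx (1.70 ± 0.54), Il1r1 (1.37 ± 0.58), Rora (1.01 ± 0.55) and Maf (0.97 ± 0.31) had positive and Gata3 (-1.11 ± 0.28) and Slamf6 (-1.21) negative differences, each with an adjusted p of 1. IL-6/STAT3 response genes had a median of 0.21 (camera adjusted p = 0.00367, adjusted p = 0.219 with an estimated correlation). Their call was lost without replicate 2 of IL-6 with IL-1β (adjusted p = 0.0606) and without replicate 2 with IL-23 (adjusted p = 0.0894). NK receptor genes had a median of 0.66 (camera adjusted p = 0.0136, adjusted p = 0.356 with an estimated correlation). This call was lost without replicate 1 of IL-6 with IL-1β (adjusted p = 0.379) and without replicate 2 with IL-23 (adjusted p = 0.706). The mean of 0.48 was 0.74 without replicate 2 of IL-6 with IL-1β and 0.87 without replicate 1 with IL-23. Cell cycle genes had lower values with IL-23 in 30 of 31 cases (median -0.59, camera adjusted p = 1.32e-13, adjusted p = 0.335 with an estimated correlation). Mki67, which marks cycling cells, had signals of 4187 ± 1830 against 6849 ± 546. Without replicate 1 with IL-23 the list was not called (mean 0.03, adjusted p = 0.566), while without replicate 2 its mean went from -0.55 to -1.14. The published pathogenic list had a median of -0.03 and a mean of 0.10 and was not called.

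IL-6 with IL-1β, compared with no cytokine, turned on Il17a and Il21. Il21, which encodes a cytokine that amplifies Th17 differentiation, rose 133-fold, from 12.3 ± 1.98 to 4274 ± 319 (log2 fold change 7.05 ± 0.22, adjusted p = 2.61e-06). Il17a rose 43.5-fold, from 55.4 ± 12.9 to 3332 ± 1110 (5.44 ± 0.28, adjusted p = 5.93e-05). Gata3 fell 8.8-fold, from 3115 ± 497 to 334.6 ± 25.8 (-3.14 ± 0.28, adjusted p = 0.00142). Over all genes 200 rose and 65 fell, or 179 and 105 after scaling each array to the same median.

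Lum, the gene of a matrix proteoglycan, rose 136-fold, from 75.35 ± 5.3 to 12940 ± 1320 (adjusted p = 6.62e-06). Timp1, which encodes an inhibitor of matrix metalloproteinases, rose 109-fold, from 56.35 ± 7.28 to 9148 ± 5500 (adjusted p = 0.000408). Ermn (6.60, adjusted p = 0.000856), S100a6 (5.78, adjusted p = 0.0158), Crispld2 (5.49, adjusted p = 0.0131), Maf (4.17 ± 0.31, adjusted p = 0.000856) and Cxcr3 (3.07 ± 0.31, adjusted p = 0.00326) rose too. S100a6 lost its call without replicate 1 or 2 of IL-6 with IL-1β (adjusted p = 0.117 and 0.101) and ranged from 4.04 to 7.52 without replicate 1 or 2 of no cytokine. Crispld2 lost its call without those of IL-6 with IL-1β (adjusted p = 0.107 and 0.0682) and without replicate 1 of no cytokine (4.29, adjusted p = 0.0618), and stood at 6.69 without replicate 2. Stfa3 (-5.37 ± 0.61, adjusted p = 0.00453), Bmp2 (-5.03, adjusted p = 0.016), Shtn1 (-4.79, adjusted p = 0.0125), Cd83 (-4.55 ± 0.60, adjusted p = 0.0094), Lad1 (-4.34, adjusted p = 0.0126) and Penk (-4.11, adjusted p = 0.0094) fell. Tbx21 rose (3.77 ± 0.77, adjusted p = 0.0453) but lost the call without replicate 1 or 2 of IL-6 with IL-1β (adjusted p = 0.309 and 0.0901) or of no cytokine (adjusted p = 0.084 and 0.0715). Il24 (5.36 ± 1.10, adjusted p = 0.0453) kept its call in 7 of 16 other settings. Il10 had a difference of 0.04 (95% interval -0.67 to 0.75). Il9 had 0.02 with a wide interval (95% interval -2.28 to 2.31), since its arrays went both ways (686.9 and 140.7 against 86.3 and 1024.7). Ahr (2.03, adjusted p = 0.109) and Csf2 (-1.36, adjusted p = 0.433) did not pass.

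IL-6/STAT3 response genes leaned higher with IL-6 and IL-1β, with Il21, Socs3 (3.97 ± 0.49, adjusted p = 0.00651), Bcl3 (3.38, adjusted p = 0.0145) and Fosl2 (1.53, adjusted p = 0.0226) past the test among 14 (median 1.00, camera adjusted p = 2.3e-05, adjusted p = 0.176 with an estimated correlation). Of 10 Th17 genes, Il17a and Il21 rose and 6 rose over the list alone (median 1.54, camera adjusted p = 1.19e-06, adjusted p = 0.183 with an estimated correlation). Of 15 Th1 genes Cxcr3, Il12rb2 (4.03, adjusted p = 0.0125) and Tbx21 rose and Fasl fell (-3.50, adjusted p = 0.044). Over the list alone 7 rose and 1 fell (median 0.86, camera adjusted p = 0.0071, adjusted p = 0.183 with an estimated correlation). Of 7 Th2 genes Gata3 and Il4 (-2.88, adjusted p = 0.0164) fell and Il24 rose (median -1.33, camera adjusted p = 0.018, adjusted p = 0.21 with an estimated correlation). Of 7 non-pathogenic genes Maf, Il1rn (4.06, adjusted p = 0.0208) and Ikzf3 (1.83, adjusted p = 0.0341) rose (median 1.83, camera adjusted p = 0.0071, adjusted p = 0.183 with an estimated correlation). The Th1 and the non-pathogenic list lost their calls without replicate 2 of no cytokine (adjusted p = 0.0642 and 0.0606). The Th2 list lost its call without that array (adjusted p = 0.507) and without replicate 2 of IL-6 with IL-1β (adjusted p = 0.0624), and its mean went from -0.52 to -0.93 without replicate 1 of no cytokine.

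All 18 glycolysis and hypoxia genes had higher values with IL-6 and IL-1β (median 0.60, camera adjusted p = 0.000175, adjusted p = 0.487 with an estimated correlation), with none past the test singly. Much of this came from replicate 1 of no cytokine: the list mean of 0.83 was 0.26 without it (adjusted p = 0.0148) and 1.40 without replicate 2. Cell cycle genes leaned lower (median -0.70, camera adjusted p = 4.38e-08, adjusted p = 0.466 with an estimated correlation), again with none past it. Klrd1 (2.61, adjusted p = 0.0341), Klre1 (2.03, adjusted p = 0.0203) and Klrk1 (1.86, adjusted p = 0.0447) rose, which is all 3 NK receptor genes that passed the filter (median 2.03, camera adjusted p = 0.000252, adjusted p = 0.219 with an estimated correlation). Interferon-stimulated genes had a median of 0.43 with none past the test (camera adjusted p = 0.0484, adjusted p = 0.449 with an estimated correlation). That call was lost without replicate 1 or 2 of IL-6 with IL-1β (adjusted p = 0.0664 and 0.0913), replicate 1 or 2 with IL-23 (adjusted p = 0.0618 and 0.0643), or replicate 1 of no cytokine (adjusted p = 0.191). The mean of 0.39 was 0.60 without replicate 2 of no cytokine. In the pathogenic list Tbx21 rose while Ccl3 (-2.48, adjusted p = 0.024) and Il3 (-3.56, adjusted p = 0.00435) fell. That list was not called, with a median of 0.22 and a mean of 0.05 while camera pointed down. The regulatory list, with Ikzf2 up (1.38, adjusted p = 0.0329) and Nrp1 down (-2.58, adjusted p = 0.0164), had a median of 0.08 and a mean of -0.07 and was not called. Smad3 (1.99, adjusted p = 0.0294) and Smad7 (1.39, adjusted p = 0.0386) rose and Tgfbr1 fell (-1.45, adjusted p = 0.0464) in the TGF-β/SMAD list, which was not called here.

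The count of 265 genes was 43 and 41 without replicate 1 and 2 of IL-6 with IL-1β, and 93 and 1321 without replicate 1 and 2 of no cytokine. Of the 38 named genes that passed, 25, 26, 21 and 1 lost the call in those 4 fits, in that order. None changed direction, and Lum, Il21, Timp1, Ermn, Il17a, Maf, Cxcr3, Gata3, Stfa3, Il3 and Ctsw kept it in each. The other 27 lost it in at least 1.

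TGF-β1 with IL-6 and IL-1β, compared with no cytokine, gave the most genes past the test of the 6 comparisons. Il17a rose 275-fold, from 55.4 ± 12.9 to 20610 ± 2190 (log2 fold change 8.10 ± 0.28, adjusted p = 2.86e-06). Timp1 rose 267-fold, from 56.35 ± 7.28 to 20310 ± 1410 (8.06 ± 0.45, adjusted p = 4.1e-05). Penk, which encodes the enkephalin precursor, was 149-fold lower with the cytokines, at 56.25 against 11490 ± 2680 (-7.22 ± 0.54, adjusted p = 0.000181). Ccl3 was 83.8-fold lower, at 7.2 ± 3.82 against 2436 ± 1340 (-6.39 ± 0.43, adjusted p = 0.000102). Over all genes 730 rose and 478 fell, or 629 and 727 after scaling each array to the same median, so the balance of up and down rests on the scaling.

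Serpinb1a (8.00 ± 0.67, adjusted p = 0.000298), Ctla2b (7.39 ± 0.96, adjusted p = 0.00277), Pdpn (7.27 ± 0.43, adjusted p = 5.9e-05), Procr (6.96 ± 0.60, adjusted p = 0.000334), Maf (6.94 ± 0.31, adjusted p = 1.58e-05), Ahr (6.70 ± 0.54, adjusted p = 0.000248) and Il10 (5.71 ± 0.31, adjusted p = 4.1e-05) rose. Tnfsf11 (-6.90 ± 0.58, adjusted p = 0.000298), the gene of the cytokine RANKL, fell along with Akr1c18 (-6.67), Igfbp7 (-6.58) and Shtn1 (-6.53). Tbx21 (0.56, adjusted p = 0.675), Cxcr3 (-0.92, adjusted p = 0.0989), Il9 (3.23, adjusted p = 0.0789) and Csf2 (-1.64, adjusted p = 0.241) did not pass the test.

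Of 10 Th17 genes 7 rose, among them Il17a, Il21 (6.82, adjusted p = 2.86e-06) and Il1r1 (3.95, adjusted p = 0.00469). Over the list alone 8 rose (median 3.79, camera adjusted p = 1.5e-08, adjusted p = 0.176 with an estimated correlation). TGF-β/SMAD response genes rose in 5 of 16 cases, with Smad7 (2.29, adjusted p = 0.00174), Smad3 (2.66, adjusted p = 0.00347) and Ldlrad4 (3.11, adjusted p = 0.00826) among them, and Id3 fell (-2.75, adjusted p = 0.00322). When adjusted over the list alone 12 rose and 1 fell (median 1.26, camera adjusted p = 0.000114, adjusted p = 0.125 with an estimated correlation). Of 14 IL-6/STAT3 response genes 7 rose, including Socs3 (4.40, adjusted p = 0.00127). Over that list alone 10 rose (median 1.16, camera adjusted p = 2.49e-06, adjusted p = 0.166 with an estimated correlation). Of 7 non-pathogenic genes 5 rose, and 6 over the list alone (median 4.19, camera adjusted p = 5.73e-08, adjusted p = 0.0873 with an estimated correlation). Of 14 pathogenic genes 5 fell, including Il3 (-5.69, adjusted p = 0.000113), Ccl3, Ccl4 (-3.00) and Gzmb (-3.86, adjusted p = 0.036). Over their list alone 6 fell and 1 rose (median -0.94, camera adjusted p = 0.00115, adjusted p = 0.166 with an estimated correlation).

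Kif11 (-1.83, adjusted p = 0.0213) was 1 of 5 cell cycle genes that fell, against 27 of 31 over the list alone (median -1.18, camera adjusted p = 8.05e-12, adjusted p = 0.373 with an estimated correlation). Kif11 lost its call without replicate 1 of no cytokine (adjusted p = 0.096) and without replicate 2 with TGF-β1 (-1.43, adjusted p = 0.116). Among 18 glycolysis and hypoxia genes P4ha1 (2.36, adjusted p = 0.00369), Ero1a (1.86, adjusted p = 0.0413) and Slc2a1 (1.23, adjusted p = 0.0403) rose. Adjusted over the list alone, 5 rose (median 0.60, camera adjusted p = 9.29e-05, adjusted p = 0.487 with an estimated correlation). The list mean of 1.03 was 0.46 without replicate 1 of no cytokine (adjusted p = 0.00112) and 1.60 without replicate 2. Ero1a lost its call without that replicate 1 (0.97, adjusted p = 0.0506) and without replicate 1 or 2 with TGF-β1 (adjusted p = 0.21 and 0.109). All 3 NK receptor genes rose, Klrd1 (6.12, adjusted p = 0.000258) and Klre1 (5.63, adjusted p = 6.24e-05) the most (median 5.63, camera adjusted p = 2.81e-05, adjusted p = 0.183 with an estimated correlation). Ctsw, which encodes cathepsin W, rose as well (6.02, adjusted p = 6.8e-05), while Nkg7 (-4.40, adjusted p = 0.00758) and Serpinb9 (-4.54) fell, and the cytotoxic list was not called. In the Th2 list, which was not called, Gata3 (-5.48 ± 0.28, adjusted p = 2.38e-05), Il4 (-3.66, adjusted p = 0.00225) and Il13 (-2.62, adjusted p = 0.0242) fell and Il24 rose (6.22, adjusted p = 0.00995). Interferon-stimulated genes divided without a list call, with Ifih1 (-4.20) among 4 that fell and Bst2 (1.88) the 1 that rose. Their median was 0.04 and their mean -0.32, and the sign of the median depended on the scaling.

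The count of 1208 genes was 323 and 563 without replicate 1 and 2 with TGF-β1, and 510 and 2349 without replicate 1 and 2 of no cytokine. Of the 57 named genes that passed, 17, 10, 11 and 4 lost the call in those 4 fits, in that order. None changed direction, and no list lost its call. The 20 that lost it in at least 1 fit were Fasl, Gzmb, Il12rb2, Cxcr6, Il24, Il13, Ldlrad4, Il1rn, Ifih1, Xaf1, Bst2, Kif11, Ero1a, Idi1, Il7r, S1pr1, Nkg7, Flt3, Klrk1 and Car2.

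IL-23 with IL-6 and IL-1β, compared with no cytokine, raised Il17a 234-fold, from 55.4 ± 12.9 to 17510 ± 1630 (log2 fold change 7.87 ± 0.28, adjusted p = 2.46e-06). Lum rose 201-fold, from 75.35 ± 5.3 to 19150 ± 1740 (7.65 ± 0.27, adjusted p = 2.46e-06), and Tbx21 rose from 26.75 ± 32.7 to 1090 ± 837 (4.53 ± 0.77, adjusted p = 0.0143). Gata3 was lower, at 143.6 against 3115 ± 497 (-4.25, adjusted p = 0.000175). Over all genes 371 rose and 190 fell, or 378 and 310 after scaling each array to the same median.

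Il21 (7.33, adjusted p = 1.86e-06), Timp1 (7.74), Ermn (7.44), Crispld2 (6.66), Maf (5.13, adjusted p = 0.000172) and Ahr (2.54, adjusted p = 0.0339) rose. Tnfsf11 (-4.68), Shtn1 (-5.23), Lad1 (-5.20), Stfa3 (-4.97) and Cd83 (-4.60) fell, as did Bmp2 (-5.03), which lost its call without replicate 1 with IL-23 (adjusted p = 0.0585). Il10 (0.15, adjusted p = 0.807), Il9 (-1.37, adjusted p = 0.449) and Csf2 (-1.60, adjusted p = 0.292) did not pass.

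Of 15 Th1 genes 7 rose, among them Tbx21, Cxcr3 (3.26, adjusted p = 0.00116), Il12rb2 (4.42, adjusted p = 0.00441), Hlx (4.03, adjusted p = 0.00457) and Il18r1 (2.51, adjusted p = 0.0389), and Fasl fell (-3.74, adjusted p = 0.0223). The list median was 0.68 (camera adjusted p = 0.00884, adjusted p = 0.183 with an estimated correlation). Of 10 Th17 genes 5 rose, including Il1r1 (4.11, adjusted p = 0.0063) and Rora (3.15, adjusted p = 0.0154). Adjusted over the list alone, 7 rose (median 1.9, camera adjusted p = 2.49e-07, adjusted p = 0.183 with an estimated correlation). IL-6/STAT3 response genes rose in 5 of 14 cases, including Socs3 (4.43, adjusted p = 0.00215). Adjusted over the list alone, 10 rose and 2 fell (median 1.21, camera adjusted p = 4.92e-06, adjusted p = 0.166 with an estimated correlation). Of 7 non-pathogenic genes 4 rose (Ahr, Ikzf3, Il1rn, Maf). Over their list alone 4 rose and 1 fell (median 1.82, camera adjusted p = 0.0116, adjusted p = 0.183 with an estimated correlation). Of 7 Th2 genes Il24 rose (6.25, adjusted p = 0.0161) and Gata3 and Il4 (-3.59, adjusted p = 0.0039) fell (median -1.70, camera adjusted p = 0.0484, adjusted p = 0.263 with an estimated correlation). Without replicate 2 of no cytokine the Th1, non-pathogenic and Th2 lists lost their calls (adjusted p = 0.0506, 0.0645 and 0.533). The Th2 list also did so without replicate 1 of no cytokine (mean -1.09 against -0.68 with all arrays, adjusted p = 0.0777) or with IL-23 (adjusted p = 0.0686).

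Cell cycle genes fell in 6 of 31 cases, including Kif11 (-1.89, adjusted p = 0.0308) and Ccna2 (-1.69, adjusted p = 0.0439), and in 25 over the list alone (median -1.28, camera adjusted p = 1.96e-13, adjusted p = 0.335 with an estimated correlation). Replicate 1 with IL-23 carried a good part of this: without it the list mean went from -1.27 to -0.68 (adjusted p = 8.3e-09), and Kif11 (-1.35, adjusted p = 0.194) and Ccna2 (-1.10, adjusted p = 0.236) lost their calls. Both also lost them without replicate 1 of no cytokine (adjusted p = 0.136 for Kif11 and 0.204 for Ccna2). Glycolysis and hypoxia genes leaned higher, with none of 18 past the test and 4 up over the list alone (median 0.62, camera adjusted p = 5.54e-05, adjusted p = 0.487 with an estimated correlation). Their mean of 0.91 was 0.33 without replicate 1 of no cytokine (adjusted p = 0.00108) and 1.48 without replicate 2. Klrd1 (2.71), Klre1 (2.70) and Klrk1 (2.53) rose among the NK receptor genes (median 2.7, camera adjusted p = 0.0002, adjusted p = 0.219 with an estimated correlation). Interferon-stimulated genes had 1 of 19 past the test and a median of 0.48 (camera adjusted p = 0.0474, adjusted p = 0.449 with an estimated correlation). That call was lost without replicate 1 or 2 of IL-6 with IL-1β (adjusted p = 0.0549 and 0.0529), replicate 1 or 2 with IL-23 (adjusted p = 0.101 and 0.0608), or replicate 1 of no cytokine (adjusted p = 0.191). Without replicate 2 of no cytokine the mean went from 0.42 to 0.63. In the pathogenic list, which was not called, Tbx21, Ccl5 and Il18r1 rose and Ccl3 and Il3 (-4.10, adjusted p = 0.00116) fell. The regulatory list, also not called, had a median of 0.21 and a mean of -0.27.

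The count of 561 genes was 131 and 531 without replicate 1 and 2 with IL-23, and 220 and 1846 without replicate 1 and 2 of no cytokine. Of the 47 named genes that passed, 25, 11, 15 and 1 lost the call in those 4 fits, in that order. None changed direction, and Tbx21 lost its call without replicate 1 with IL-23 (adjusted p = 0.129). Kept in each were Il17a, Timp1, Lum, Ermn, Il21, Crispld2, Shtn1, Lad1, Stfa3, Tnfsf11, Cd83, Gata3, Il4, Nrp1, Socs3, Il3, Maf, Ctsw, Klre1, Klrk1 and Cxcr3, and the other 26 lost the call in at least 1.

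In the pair of cultures with IL-6 and TGF-β, each with 1 array and so without a test, blocking the TGF-β receptor went with a signal of 135 for Il17a against 9368 without the inhibitor, 60.6-fold lower. Il10 was 67.1-fold lower with the inhibitor (32 against 3467), Ahr 22.9-fold lower (269 against 6595) and Maf 5.27-fold lower (1255 against 6702). Gzmb, which encodes granzyme B, was 149-fold higher with the inhibitor (19383 against 110), and Tbx21 was 9.47-fold higher (842 against 71). Of 10813 genes counted, 302 were more than 2-fold higher and 228 more than 2-fold lower with the inhibitor. Such folds depend on the scaling and on the added constant: the log2 ratio of Gzmb ran from 6.68 to 7.85 over the settings, that of Il10 from -6.87 to -4.99 and that of Il17a from -6.46 to -5.46.

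Nkg7 (3061 against 55), Ms4a4b (8178 against 209), Ifitm3 (4123 against 114), Slc17a6 (1250 against 25) and Il3 (2116 against 56) were also among the largest values in favour of the inhibitor. Gcnt2 (22 against 2644), Pdpn (126 against 6993), Ctla2b (264 against 10142), Kctd14 (47 against 2181) and Il9 (90 against 3581) were among the largest the other way, and Csf2 differed little (675 against 602, 1.12-fold). Of the published pathogenic genes, 10 of 13 counted were more than 2-fold higher with the inhibitor (median log2 ratio 1.81), while all 7 non-pathogenic genes were more than 2-fold lower (median -2.4). Th1 genes were more than 2-fold higher in 8 of 15 cases (median 1.10), with Cxcr3 at 1562 against 196, and lower in 1, Cxcr6 (52 against 627). Th17 genes were lower in 5 of 10 cases (median -1.23). TGF-β/SMAD response genes were lower in 7 of 14 cases, with Skil at 458 against 3261 and Pmepa1 at 248 against 2549 (median -0.85). Id3 was the 1 that was more than 2-fold higher (528 against 88). Interferon-stimulated genes were higher in 7 of 18 cases and lower in 1, Bst2 (median 0.79). Cytotoxic genes were higher in 5 of 8 cases and lower in 2, Klrd1 (448 against 5424) and Ctsw (1261 against 7133), with a median of 1.53. Regulatory T cell genes went both ways, 3 of 12 higher and 4 lower (median -0.328). None of 31 cell cycle genes differed by more than 2-fold (median 0.11). Gzmb is in the pathogenic, Th1 and cytotoxic lists, so these lists are not separate from each other.

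Across 10813 genes, the log2 changes with added TGF-β1 and with the inhibitor, which share no arrays, were set against each other with the sign of the inhibitor ratio reversed (Pearson r = 0.726, Spearman rho = 0.496, taken across genes that are not independent of each other). Of the 98 genes that passed the test with TGF-β1, 96 were among the genes counted in the pair. The 49 higher ones of these were all lower with the inhibitor, 46 of them by more than 2-fold, against 2.11% of all genes counted. The 47 lower ones were all higher with the inhibitor, 40 of them by more than 2-fold, against 2.79% of all genes. Il10, Pdpn, Ahr and Il17a were in the first set, and Nkg7, Cxcr3 and Trat1 in the second.

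**Figure D3:**
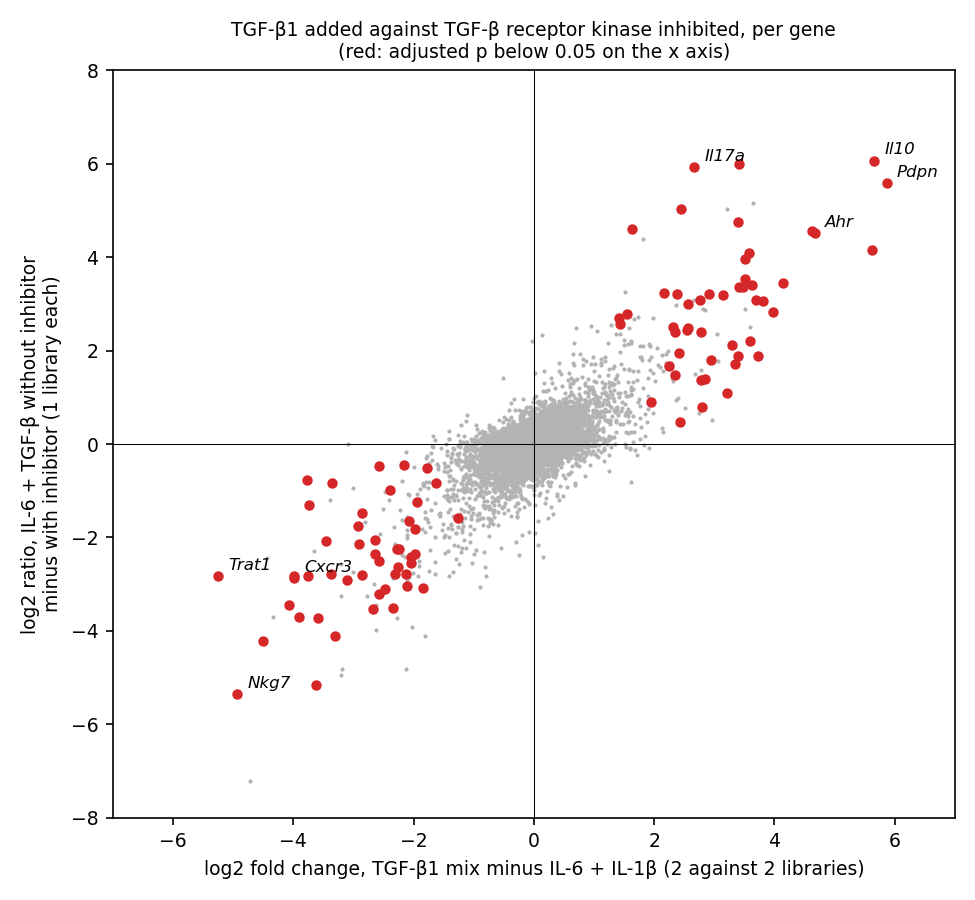
Log2 fold change with TGF-β1 added to IL-6 and IL-1β against the log2 ratio without to with the receptor inhibitor. Each point is 1 of 10813 genes counted in the pair. Red marks the 96 of them, out of 98 in all, that passed the test with TGF-β1, which all had the same sign on both axes.

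Apart from the NK receptor genes, which camera called in all 6 comparisons, the lists for other cell types were called only for B cell genes in 1 comparison. These genes had a median of -0.32 with TGF-β1 added to IL-6 and IL-1β, with none of 7 past the test (camera adjusted p = 0.0382, adjusted p = 0.487 with an estimated correlation). That call was lost without replicate 1 of IL-6 with IL-1β (adjusted p = 0.409), replicate 2 with TGF-β1 (adjusted p = 0.205), or replicate 1 or 2 of no cytokine (adjusted p = 0.0693 and 0.0738), and the mean went from -0.78 to -1.19 without replicate 2 of IL-6 with IL-1β. The lists for cholesterol synthesis, naive and memory T cells, myeloid cells and dendritic cells were never called (lowest camera adjusted p 0.0608, 0.21, 0.189 and 0.0503). The lists for CD8 T cells, for γδ and NKT cells and for erythroid cells had fewer than 3 measured members and were not tested, and of these members only Car2 passed a test (-2.42, adjusted p = 0.0412, with TGF-β1, IL-6 and IL-1β against no cytokine).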

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

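Gene counts changed with the filter, with the version of limma's fit and with the arrays left out, and no tool other than limma was run for them. A fit without 1 array has 3 residual degrees of freedom and 1 array in that group, so a lower count does not by itself single out that array. For IL-23 against TGF-β1 the count of 95 genes was 49 without a filter, 63 with a filter at the 75th percentile and 9 to 23 with 1 array left out. For TGF-β1 added to IL-6 and IL-1β the count of 98 was 65 with that filter and 15 to 50 with 1 array left out. IL-23 added to IL-6 and IL-1β gave 0 genes by limma in every setting, with 177 at an unadjusted p below 0.05.

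Against no cytokine, IL-6 with IL-1β gave 265 genes, 174 without a filter, 67 with only the 2 groups fitted and 41 to 1321 with 1 array left out. With TGF-β1 the count of 1208 was 1877 for all probe sets and 323 to 2349 with 1 array left out. With IL-23 the count of 561 was 927 for all probe sets, 258 with only the 2 groups fitted and 131 to 1846 with 1 array left out. The highest value of each range came without replicate 2 of the cultures without cytokine, and the cause was not tested. No setting reversed the direction of a named gene that had passed the test.

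Which direction held more genes did change with the setting. For IL-23 against TGF-β1, 54 higher and 41 lower became 48 and 52 with an added constant of 80, 35 and 37 without a trend, and 3 and 6 or 11 and 12 without replicate 1 or 2 with IL-23. For TGF-β1 added, 50 and 48 became 36 and 49 with a constant of 1, 32 and 33 with a filter at the 75th percentile, and 72 and 72 with arrays scaled to equal medians. For TGF-β1 against no cytokine, 730 and 478 became 629 and 727 with that scaling.

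Replicate numbers, added to the model as a block, gave 146 genes for IL-23 against TGF-β1, 162 for TGF-β1 added, 0 for IL-23 added, and 375, 1633 and 804 against no cytokine for IL-6 with IL-1β alone, with TGF-β1 and with IL-23. For TGF-β1 added the split was then 78 higher and 84 lower. The block kept 47 of 50 list calls. Among the named genes 22 calls were gained, including Tbx21 and Gzmb for TGF-β1 added (adjusted p = 0.00484 for Tbx21 and 0.00403 for Gzmb) and for IL-23 against TGF-β1 (adjusted p = 0.00324 for Tbx21 and 0.00556 for Gzmb), and 4 were not kept. Deviations of replicates from their group mean correlated between the 3 cytokine groups (0.499, 0.428 and 0.373) but not with the cultures without cytokine (0.0594, 0.00751 and -0.00418), and the third principal component (13% of the variance) placed replicate 1 below 0 and replicate 2 above 0 in all 4 groups. This is a hint of shared structure from the data. The labels do not say what a number stands for and there are only 2 numbers, so they were not used as pairs.

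Camera called 50 of 114 list tests, 33 up and 17 down. With the correlation estimated from the data it called 0 (lowest adjusted p = 0.0638), fry called 31, and leaving out 1 array gave 45 to 56 calls. The calls by camera therefore rest on the preset correlation, while fry, which does not use it, kept 28 of the 50. Fry asks whether the genes of a list change at all, and camera whether they change more than other genes. The calls kept by fry thus do not stand in for those of camera.

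In the inhibitor pair 530 genes passed 2-fold and 164 passed 4-fold, while 671 passed 2-fold under quantile normalization and 420 with an added constant of 80. Of 19 named genes in the pair, the ratios of 12 moved under quantile normalization, 10 with a constant of 80, 3 with a constant of 1 and 2 with the mean of a gene's probe sets, and none changed sign. Gcnt2 went from -5.99 to -2.73 with the mean of its probe sets. The correlation of 0.726 between added TGF-β1 and the inhibitor was 0.777 with a filter at the 75th percentile and 0.634 to 0.689 with 1 array left out.

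Scaling each array to the same median moved the median of all genes from -0.02 to 0.09 for IL-23 added, and against no cytokine from 0.05 to -0.16 for IL-6 with IL-1β and from 0.06 to -0.12 with TGF-β1. This scaling moves all genes of an array alike, so values relative to the median of all genes cannot change with it. By that measure cell cycle genes stood at -0.58, -0.75 and -1.24 in these comparisons with the deposited scaling. Under quantile normalization over 10 arrays they stood at -0.588, -0.735 and -1.21. The median of some lists changed sign under a scaling: Th2 (IL-23 against TGF-β1, IL-23 added), IL-6/STAT3 and cell cycle (IL-23 against TGF-β1), glycolysis (both of these comparisons), pathogenic and cholesterol (IL-23 added), naive and memory (IL-23 added, IL-6 with IL-1β), regulatory (IL-6 with IL-1β), interferon (TGF-β1 against no cytokine) and myeloid (TGF-β1 or IL-23 against no cytokine). Camera had called none of these. Quantile normalization of the 8 arrays was chosen after the data had been seen.

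Signals near the background limit what folds mean: with means such as 13.1 for Nkg7 with TGF-β1, the lower value lies under the 25th percentile of all signals, and the fold depends on the constant added before the logarithm.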

Other observations

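The tests on NK and CD8 T cell genes, on leaving out an array with IL-23 and on RNA degradation were chosen after the result was seen.

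Genes of naive and resting T cells went both ways with cytokines, although their list was not called. Satb1, the gene of a chromatin organiser of T cells, rose from 6071 ± 808 without cytokine to 21220 ± 2000 with TGF-β1 (1.80, adjusted p = 0.00162), a call kept without each of the 4 arrays. It rose to 16780 ± 2440 with IL-6 and IL-1β (adjusted p = 0.0125), a call lost without replicate 1 or 2 of that group (adjusted p = 0.0725 and 0.12). Slamf6, which encodes a lymphocyte surface receptor, was lower with TGF-β1 (232.6 ± 82.8 against 2079 ± 780; -3.04, adjusted p = 0.00416), also in each of those 4 fits. Il7r, which encodes the receptor for a survival cytokine, rose with TGF-β1 (7832 ± 4520 against 948.9 ± 733; 3.13, adjusted p = 0.00999) but lost the call without replicate 1 with TGF-β1 (adjusted p = 0.0792).

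Lum, Timp1 and Serpinf1, genes often studied in connective tissue, were higher with IL-6 and IL-1β than without cytokine, Serpinf1 at 13550 ± 2190 against 620.6 ± 381 (4.54 ± 0.37, adjusted p = 0.000879). Fibroblasts or other stromal cells would bring their collagens, but the median log2 change of 19 measured fibroblast genes was 0.0724 (quartiles -0.28 and 0.40), and 17 of them lay at or under the array median in at least 1 array with IL-6 and IL-1β. Col1a1 (6.4 and 32.8), Col3a1 (39.8 and 37.3) and Sparc (19.6 and 64.9) had low signals in those arrays. Of the 19 genes Mgp (1.54) and Fn1 (1.5) rose most, to signals of 32 and 69 and of 192.1 and 60.4. Dcn, which is not among the 19 but is also studied in connective tissue, went from 5.5 to 307.3 ± 204. The 19 genes as a set argue against stromal cells, though these 3 go the other way. The sort for CD4+ naive cells would have removed such cells. A response of the T cells to the cytokines remains open and was not tested.

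Klrd1 and Klre1 were higher with TGF-β1 than with IL-6 and IL-1β alone. NK or CD8 T cells would bring Nkg7, but it fell by 4.93 log2 units (value -4.93) to signals of 7.2 and 19, and Ncr1 had signals of 26.7 and 9.3. Nkg7 was also low with IL-6 and TGF-β in the inhibitor pair (55, against 3061 with the inhibitor). A low value with TGF-β1 thus cannot decide whether such cells were present. With TGF-β1, Cd8a (137.1 and 172.4) and Cd8b1 (241.1 and 319.5) lay above the array medians of 63.5 and 70.6. Cd8b1 did not rise along with Klrd1. It had signals of 294.9 and 404.2 with IL-6 and IL-1β alone and of 329.2 and 577.2 without cytokine. The 2 probe sets of Cd8a went opposite ways with added TGF-β1 (log2 fold changes of 0.725 and -0.592). Of 14 NK and CD8 T cell genes 5 were higher and 9 lower (median -0.42), with Ctsw among the higher ones at 8221.6 and 10115.3, and the sort for CD4+ cells would have removed those cell types. Both the presence of such cells and induction of these receptor genes in the CD4+ T cells remain open, and induction was not tested.

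The cell cycle list leaned lower with IL-23 than with IL-6 and IL-1β alone (median -0.59), with none of 31 genes past the test and the call lost with an estimated correlation (adjusted p = 0.335). Without replicate 1 with IL-23 the median was -0.0156, against -1.21 without replicate 2, so the pattern may belong to that array alone. Array scaling is argued against by a highest median of -0.486 under quantile normalization and median scaling. RNA degradation in that array is argued against by its beta-actin 3' to 5' ratio of 1.74, inside the range of 1.49 to 1.89 of the others. A difference in growth of that culture remains open and was not tested.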
